A study of Mus musculus with 9 samples.

How the data were processed

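RNA was measured by sequencing in 9 libraries from C57Bl/6 mouse spleen, 3 each of sorted cDC1, cDC2 and mcDC. The values were deposited by the authors as RPKM, reads per kilobase of gene length per M reads, for 14862 genes in 1 table of all libraries and in 8 files of single libraries. The files do not name the unit, which was read from the steps between values, and the RPKM values were not rescaled for composition as deposited. The mouse genome build mm8 is named in the submitters' processing notes, while the aligner, the counting tool, the gene annotation and their versions were not given in the sources used here. Each single-library file held the same values as its column, and mcDC replicate 3 had no file of its own, so results from these files are those with mcDC replicate 3 left out. There were 0 columns of other samples.

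Whole reads were recovered from the steps for 100% of the nonzero values, and the total behind each library's scaling was 0.9992 to 1.0002 of the recovered total of its listed genes. In replicates 1, 2 and 3 the recovered reads were 11.00, 11.01 and 9.68 M in cDC1, 9.19, 11.51 and 12.43 M in cDC2, and 8.22, 5.56 and 5.14 M in mcDC. A single read in a gene of 1 kb was worth 0.080 to 0.195 RPKM, and 2.71% to 12.35% of genes were at 0. A reference gene table of assembly GRCm38.p6 served for gene names alone, and 14847 of the 14862 gene numbers were found in it.

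The comparisons, the gene lists, the tests and most alternatives were written down before the data were examined, for either counts or normalized values, and the branch for normalized values was used. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) in 1 fit of the 3 groups, with a trend in the prior variance, over the 11971 genes above 1 RPKM in at least 2 libraries. There were 6 residual degrees of freedom, the median prior added 3.4, and the median standard error was 0.209. P-values were adjusted by the Benjamini and Hochberg method within each comparison, and genes were called at an adjusted p threshold of 0.05. Fold changes on this scale understate the ratio for genes of low RPKM. Means and SDs are of RPKM over 3 libraries. Genes higher or lower in mcDC than in both other subsets were those called in the same direction against each.

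A set of 34 lists of textbook genes for cell types and functions was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of the listed names 95.7% were matched in the table. Named genes were chosen by rule. For each comparison these were the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the libraries, leaving out predicted and sex-linked genes. For each list described, up to 4 members called in the commoner direction with the largest change and up to 2 other members with the highest CPM could be named, and 14 dendritic cell genes are always given. For genes higher or lower in mcDC than in both others, these were the 10 with the largest change, taking the smaller of the 2. A few genes are not reported here. Other genes are named as chosen after their values were seen.

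The library titles run in consecutive numbers in which each run of 3 holds 1 library of each subset, and the runs were taken as replicates 1, 2 and 3. The labels do not say what a run shares. Deviations from the group means were correlated over 7149 genes between libraries of different subsets. All 9 pairs of the same run had a positive correlation, 0.12 to 0.61 with a mean of 0.39. Other pairs had -0.62 to 0.03 with a mean of -0.19. Deviations cancel within a group, so this negative mean follows largely from the positive one. Of the libraries, 9 of 9 correlated best with their own run. The title run was therefore also fitted as a replicate block, and its result stands beside a result that it changes.

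Alternatives were quantile normalization, a pseudocount of 0.1, no filter, a filter of 5 CPM in 2 libraries, fits of the 2 groups compared alone, no trend in the prior variance, the title run as a block, and leaving out each library in turn. After the data were seen, median-of-ratios scaling, voom on the recovered reads, thinning of all libraries to one depth, and the block with mcDC replicate 3 left out were added, and voom was run for counts and named genes only. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

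The main test was tested on simulated data built from the means and totals of the libraries. For mcDC against cDC1 (11668 genes) it recovered 45% of genes changed 2-fold and 91.9% of those changed 4-fold, with 6.2% false calls. For mcDC against cDC2 (11685 genes) these were 51%, 90% and 3.4%, and for cDC1 against cDC2 (11673 genes) 42%, 91% and 4.3%. Changed genes were drawn from those with a mean of at least 5 CPM. Each gene had a spread pooled over the groups, drawn independently for each library. The rates therefore leave out the wider spread of the mcDC replicates and the shared deviations within a title run, and may be too favourable for mcDC.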

Results

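Gene expression was measured by RNA sequencing in 3 dendritic cell subsets sorted from the spleens of C57Bl/6 mice aged 8 to 12 weeks. The subsets were type 1 conventional dendritic cells (cDC1), which cross-present antigen from dead cells to CD8 T cells, type 2 conventional dendritic cells (cDC2), which mainly present antigen to CD4 T cells, and a further subset labelled mcDC. In the field this abbreviation is used for merocytic dendritic cells, although the labels do not expand it, and the surface markers used for the sort were not given in the sources used here. Each subset had 3 libraries, 9 in all. Library totals were 9.68 to 11.01 M reads in cDC1, 9.19 to 12.43 M in cDC2 and 5.14 to 8.22 M in mcDC, so that 1 read in a gene of 1 kb was worth between 0.080 and 0.195 RPKM. The labels do not say whether the libraries of a subset came from separate animals, so p-values measure the spread between these libraries, which may be technical.

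Replicates 1, 2 and 3 follow the runs of consecutive library titles, each with 1 library of every subset (the title run below). Replicate libraries of a subset differed by more than counting noise, with a chi-square per degree of freedom between 9.76 and 62.1 over the 9 pairs. Across genes, which are not independent replicates, Pearson's r between replicates was 0.898 to 0.990. The first principal component held 46.4% of the variance and placed cDC1 (-55.0 to -39.0) apart from cDC2 (35.5 to 36.6), with mcDC at 7.6 to 20.5. The second component held 25.9% and set mcDC replicate 3 at -73.6, the shallowest library, with 12.35% of genes at 0, apart from the other 8.

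**Figure D1:**
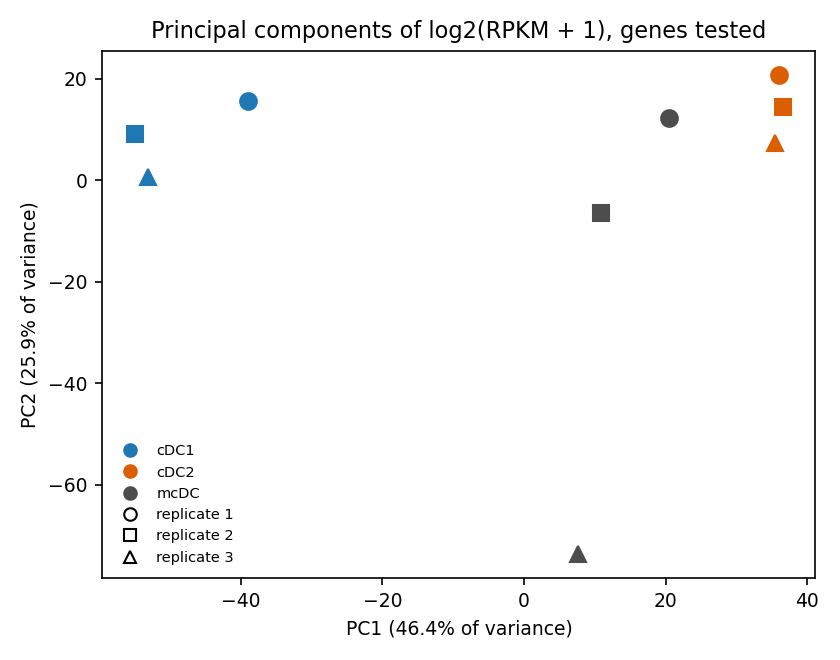
Principal components of log2(RPKM + 1) over the genes tested, PC1 (46.4% of the variance) on the x axis and PC2 (25.9%) on the y axis, with colour for the subset and symbol for the replicate. The mcDC libraries lie between cDC1 and cDC2 on PC1, at 7.6 to 20.5, and mcDC replicate 3 lies at -73.6 on PC2.

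cDC1 and cDC2 differed in the transcripts by which the subsets are known. Cd8a (Entrez gene 12525), which encodes the CD8 alpha chain carried by splenic cDC1, was at 332 ± 22.6 RPKM in cDC1 and 1.30 ± 0.101 in cDC2 (mean ± SD, 3 libraries each), a log2 fold change of 7.18 ± 0.27 (SE, limma adjusted p = 6.9e-07). Xcr1 (23832), a chemokine receptor that recruits cDC1 towards XCL1, was at 159 ± 24.2 against 2.45 ± 0.442 RPKM (log2 fold change 5.54 ± 0.23, adjusted p = 9.4e-07). Clec9a (232414), a receptor for actin exposed by dead cells, was at 325 ± 24.3 against 20.5 ± 3.67 RPKM (3.93 ± 0.18, 1.7e-06). cDC2 carried more Itgam (16409), the CD11b integrin chain, at 101 ± 18.4 against 3.23 ± 0.698 RPKM (-4.59 ± 0.21, 1.7e-06), more Ace (11421), angiotensin-converting enzyme, at 94.0 ± 11.5 against 0.688 ± 0.308 RPKM (-5.82 ± 0.16, 8.8e-08), and more Tgm2 (21817), a transglutaminase, at 208 ± 16.1 against 5.15 ± 0.321 RPKM (-5.08 ± 0.10, 1.2e-08).

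In all, 2344 of 11971 genes tested passed the limma threshold of adjusted p 0.05 between cDC1 and cDC2, 1059 higher and 1285 lower in cDC1, of which 582 and 744 differed by at least 2-fold. The libraries of the 2 subsets did not overlap at 5516 genes (46.1%), where chance gives 10%. Without cDC1 replicate 2 the count was 1547, with these groups fitted alone 3724, and with the title run as a block and mcDC replicate 3 left out 4274. Ttc39a (230603) and P3h2 (210530), a collagen prolyl hydroxylase, were among the 5 largest rises in cDC1, with log2 fold changes of 5.62 ± 0.20 and 4.98 ± 0.49. Mab21l3 (242125) was at 37.7 ± 2.65 RPKM in cDC1 and at 0.0679 ± 0.0268 in cDC2, a level that rests on a few reads per library. Irf8 (15900), the transcription factor that drives cDC1 development, was at 727 ± 92.8 against 76.3 ± 22.7 RPKM (adjusted p = 0.00011). Siglech (233274), a plasmacytoid dendritic cell lectin, was at 8.71 ± 7.0 against 0.684 ± 0.0839 (0.0032). Flt3 (14255), the dendritic cell growth factor receptor, was at 265 ± 18.6 against 146 ± 14.9 (0.0021). Cd4 (12504) was lower in cDC1, at 11.7 ± 7.82 against 100 ± 20.6 RPKM (adjusted p = 0.00087). Itgax (16411), the CD11c integrin chain, was at 270 ± 33.2 in cDC1 and 462 ± 54.3 RPKM in cDC2 (adjusted p = 0.018). Its adjusted p was 0.072, 0.080, 0.073 and 0.066 without cDC1 replicate 2, cDC1 replicate 3, cDC2 replicate 1 and cDC2 replicate 2, and 0.00030 to 0.080 over all settings tried. Zbtb46 (72147), a transcription factor of conventional dendritic cells, was at 40.5 ± 3.30 and 34.6 ± 4.72 RPKM and did not pass (adjusted p = 0.51).

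Gene lists fixed from textbook markers were compared with camera at its preset correlation, which called 15 of 34 lists between cDC1 and cDC2, 6 higher and 9 lower in cDC1. With an estimated correlation camera called 0 lists (6 at an unadjusted p under 0.05), and fry, which asks only whether a list's members move on balance one way, called 20. Of 22 cDC1 identity genes, 21 were higher in cDC1 (22 adjusted over the list alone, camera adjusted p = 1.1e-24, adjusted p = 0.11 with an estimated correlation). Itgae (16407), the CD103 integrin chain, was at 41.1 ± 23.6 against 0.360 ± 0.0759 RPKM. Cd207 (246278), langerin, was at 26.8 ± 6.93 against 0.0885 ± 0.111 RPKM. The remaining member, Batf3 (381319), a transcription factor needed for cDC1 development, was at 171 ± 4.69 against 118 ± 5.73 RPKM (adjusted p = 0.079, and 0.040 with the title run as a block). Of 23 cDC2 identity genes, 21 were lower and 1 higher in cDC1 (22 and 1 adjusted over the list alone, camera adjusted p = 1.3e-16, adjusted p = 0.12 with an estimated correlation). Sirpa (19261), an inhibitory receptor for CD47, was at 22.7 ± 17.7 against 274 ± 6.33 RPKM (log2 fold change -3.78 ± 0.40). Clec4a4 (474145), the DCIR2 lectin, was at 3.98 ± 4.71 against 78.0 ± 8.88 RPKM (-4.46 ± 0.62). Clec4a1 (269799) and Clec4a3 (73149), with log2 fold changes of -5.25 ± 0.28 and -5.10 ± 0.25, belong with Clec4a4 to a family of near-identical genes whose reads could have been split between copies, so their values are uncertain. Irf4 (16364), a transcription factor of cDC2, was at 12.1 ± 9.78 against 27.1 ± 8.08 RPKM (adjusted p = 0.11, and 0.0027 with the title run as a block).

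Genes of maturation and of class I antigen presentation were higher in cDC1. Of 22 mature and migratory dendritic cell genes, 12 were higher and 2 lower in cDC1 (13 and 2 adjusted over the list alone, camera adjusted p = 4.3e-07, adjusted p = 0.25 with an estimated correlation). Il12b (16160), a subunit of the cytokine IL-12, was at 47.6 ± 7.60 against 1.57 ± 0.853 RPKM. Ccl22 (20299), a chemokine that attracts CCR4-bearing T cells, was at 58.8 ± 5.04 against 5.07 ± 1.5 RPKM. Ccr7 (12775), the receptor for migration to lymph nodes, was at 231 ± 28.3 against 51.3 ± 33.6 RPKM. Of 24 MHC class I presentation genes, 11 were higher in cDC1 (14 adjusted over the list alone, camera adjusted p = 4.1e-06, adjusted p = 0.25 with an estimated correlation), led by the class I transactivator Nlrc5 (434341), with a log2 fold change of 1.49 ± 0.16, and by Wdfy4 (545030), which is needed for cross-presentation, with 1.21 ± 0.16. The class I heavy chain H2-K1 (14972) did not pass, at 925 ± 18.5 and 895 ± 66.6 RPKM (adjusted p = 0.88).

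Of 35 interferon stimulated genes, 21 were lower and 4 higher in cDC1 (21 and 4 adjusted over the list alone, camera adjusted p = 1.8e-07, adjusted p = 0.23 with an estimated correlation). The antiviral RNA sensor Oas2 (246728) was at 0.424 ± 0.456 against 25.2 ± 3.22 RPKM and Oasl2 (23962) at 2.09 ± 0.394 against 24.2 ± 4.87. Of 29 Toll-like and nucleic acid sensors, 17 were lower and 3 higher (17 and 4 adjusted over the list alone, camera adjusted p = 0.00049, adjusted p = 0.11 with an estimated correlation). Tlr7 (170743), a receptor for single-stranded RNA, was at 2.29 ± 1.63 against 35.2 ± 1.17 RPKM. Ddx58 (230073), which encodes the RNA sensor RIG-I, was at 1.81 ± 0.164 against 18.2 ± 1.23. Fc and complement receptors were lower at 11 and higher at 2 of 19 members (12 and 2 adjusted over the list alone, camera adjusted p = 2.3e-06, adjusted p = 0.12 with an estimated correlation). Fcer1g (14127), the common Fc receptor chain, was at 71.5 ± 35.8 against 517 ± 91.3 RPKM. C-type lectins (17 lower and 7 higher of 30, the same counts adjusted over the list alone, camera adjusted p = 0.0090), genes of apoptotic cell uptake (10 lower and 4 higher of 23, 12 and 4 adjusted over the list alone, adjusted p = 0.0090) and genes of the phagosomal NADPH oxidase and proton pump (9 lower and 1 higher of 21, the same adjusted over the list alone, adjusted p = 0.0027) were also called lower in cDC1. With an estimated correlation these 3 lists had adjusted p = 0.40, 0.37 and 0.25. The oxidase subunit Cybb (13058) was at 32.5 ± 26.2 against 178 ± 6.95 RPKM. Cd300lf (246746), a phosphatidylserine receptor, was at 5.90 ± 4.36 against 60.3 ± 9.30.

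Markers of other blood cells also differed between the conventional subsets. Of 15 neutrophil genes, 12 were lower in cDC1 (13 adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.25 with an estimated correlation). Of 17 monocyte genes, 12 were lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 9.7e-07, and 0.29 with an estimated correlation). The mean log2(RPKM + 1) of the neutrophil list was 2.63, 4.62 and 5.05 in cDC2 replicates 1, 2 and 3, and 1.10 ± 0.42 in cDC1. S100a8 (20201), a granulocyte calcium-binding protein, was at 345 ± 286 RPKM in cDC2 and 7.44 ± 6.35 in cDC1 (adjusted p = 0.0094, 8.2e-06 to 0.067 over all settings tried). The monocyte gene Lyz2 (17105), lysozyme, was at 1110 ± 386 against 96.0 ± 17.3 RPKM. T cell genes were higher at 5 and lower at 1 of 17 members (7 and 1 adjusted over the list alone, camera adjusted p = 4e-04, adjusted p = 0.40 with an estimated correlation). Cd8b1 (12526) was at 10.4 ± 2.10 against 0.338 ± 0.0303 RPKM. The list of stroma and endothelium (2 higher of 4, 2 adjusted over the list alone) had a camera adjusted p = 0.025, adjusted p = 0.25 with an estimated correlation, 0.051 without cDC1 replicate 1 and 0.012 to 0.14 over all settings tried. The erythroid and platelet list was called with camera adjusted p = 0.032 (0.62 with an estimated correlation) while 0 of its 12 members passed limma (1 at an unadjusted p under 0.05). It lost the call without cDC1 replicate 2 (0.10), cDC1 replicate 3 (0.19) or cDC2 replicate 1 (0.076), with 0.00011 to 0.19 over all settings tried. Its mean log2(RPKM + 1) was lowest in replicate 1 of every subset. In replicates 1, 2 and 3 it was 0.58, 3.11 and 3.10 in cDC1, 0.49, 1.28 and 1.17 in cDC2, and 0.65, 2.86 and 2.55 in mcDC. Of its 20 listed names 12 were matched, none of them a haemoglobin gene. With the title run as a block camera called 3 further lists, which had adjusted p = 0.40, 0.62 and 0.69 with an estimated correlation and no block. These were MHC class II presentation (7 lower and 1 higher of 19 without the block, 7 and 2 adjusted over the list alone, adjusted p from 0.085 to 0.035) and dissociation stress (2 lower of 22, 1 adjusted over the list alone, 0.14 to 0.0038), lower in cDC1, and NK cells (1 higher of 15, 1 adjusted over the list alone, 0.085 to 0.031), higher in cDC1.

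mcDC carried much less of the cDC1 transcripts than cDC1 and more of several lectin and complement transcripts. Cd8a was at 5.81 ± 3.36 RPKM in mcDC and 332 ± 22.6 in cDC1 (log2 fold change -5.72 ± 0.27, limma adjusted p = 5e-06). Xcr1 was at 15.7 ± 4.73 against 159 ± 24.2 (-3.30 ± 0.23, 3.4e-05). Clec9a was at 60.9 ± 13.9 against 325 ± 24.3 (-2.42 ± 0.18, 4.9e-05) and Cd207 at 0.459 ± 0.419 against 26.8 ± 6.93 (-4.26 ± 0.27, 2.2e-05). Ryr3 (20192), a calcium release channel, was at 24.1 ± 6.63 RPKM in mcDC and 0.271 ± 0.351 in cDC1 (4.30 ± 0.31, 4.2e-05). Tgm2 was at 99.2 ± 3.16 against 5.15 ± 0.321 (4.03 ± 0.10, 1e-07). Sirpb1a (320832), Clec4a1 and Clec4a4 completed the 5 largest rises, with log2 fold changes of 4.05 ± 0.49, 3.84 ± 0.28 and 3.84 ± 0.62, and all belong to families of near-identical genes. Dkk3 (50781), a secreted relative of Wnt inhibitors, was at 25.3 ± 4.71 RPKM in cDC1 and at 0.171 ± 0.210 in mcDC, where it rests on a few reads.

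Between mcDC and cDC1, 1845 of 11971 genes passed limma, 1141 higher and 704 lower in mcDC (61.8% higher), of which 608 and 369 differed by at least 2-fold. The libraries did not overlap at 3654 genes (30.5%, chance gives 10%). Rescaling for composition changed the balance of directions, with 877 higher and 932 lower after quantile normalization (48.5% higher), 866 and 939 with median-of-ratios scaling (48.0%) and 858 and 933 with voom (47.9%), and it moved the median log2 fold change of all genes from 0.094 to -0.017 under median-of-ratios scaling. Without cDC1 replicate 2 the count was 951, without cDC1 replicate 3 it was 1133, with these groups fitted alone 1097, and with the title run as a block and mcDC replicate 3 left out 3003. Itgae was lower in mcDC (log2 fold change -3.55 ± 0.49), and Sirpa (3.07 ± 0.40), Itgam (1.79 ± 0.21) and Cd4 (2.29 ± 0.45) were higher. Batf3 (184 ± 56.8 and 171 ± 4.69 RPKM, adjusted p = 0.86), Itgax (325 ± 81.7 and 270 ± 33.2, 0.45), Zbtb46 (34.9 ± 9.43 and 40.5 ± 3.30, 0.46) and Siglech (4.03 ± 1.02 and 8.71 ± 7.0, 0.27) did not pass. Irf8 was at 368 ± 147 and 727 ± 92.8 RPKM (adjusted p = 0.056) and Irf4 at 24.4 ± 13.3 and 12.1 ± 9.78 (0.20), and with the title run as a block both passed (0.0024 and 0.0098). Flt3 was lower in mcDC, at 174 ± 26.3 against 265 ± 18.6 RPKM (adjusted p = 0.018, 0.061 without cDC1 replicate 1, 0.065 without cDC1 replicate 2, and 0.0047 to 0.065 over all settings tried).

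Camera called 11 of 34 lists between mcDC and cDC1, 8 higher and 3 lower in mcDC, while with an estimated correlation it called 0 (5 at an unadjusted p under 0.05) and fry called 18. Of 22 cDC1 identity genes, 16 were lower in mcDC (18 adjusted over the list alone, camera adjusted p = 5.4e-20, adjusted p = 0.26 with an estimated correlation). Of 23 cDC2 identity genes, 17 were higher and 1 lower (19 and 1 adjusted over the list alone, adjusted p = 6.6e-11, and 0.26 with an estimated correlation). Dtx1 (14357), a regulator of Notch signalling, was at 87.6 ± 19.1 against 5.72 ± 3.66 RPKM and Ccr6 (12458), a chemokine receptor, at 13.4 ± 7.42 against 0.386 ± 0.245. The lower member, Clec12a (232413), at 47.5 ± 11.7 against 77.2 ± 6.72 RPKM (adjusted p = 0.027), lost its call without any one of cDC1 replicates 1, 2 and 3 (0.083, 0.065 and 0.085) and mcDC replicates 1 and 2 (0.053 and 0.071), with 0.0034 to 0.085 over all settings tried. Mature and migratory genes were lower at 7 and higher at 3 of 22 members (10 and 3 adjusted over the list alone, adjusted p = 1.3e-06, and 0.39 with an estimated correlation). Il12b was at 4.52 ± 2.71 against 47.6 ± 7.60 RPKM and Ccl22 at 5.38 ± 0.879 against 58.8 ± 5.04. MHC class I presentation genes were lower at 6 of 24 members (11 adjusted over the list alone, adjusted p = 3.2e-07, and 0.26 with an estimated correlation), with log2 fold changes of -1.40 ± 0.16 for Nlrc5 and -0.83 ± 0.16 for Wdfy4, while the light chain B2m (12010) did not pass, at 1900 ± 155 and 1900 ± 101 RPKM.

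Red pulp macrophage genes were higher in mcDC than in cDC1 at 13 of 17 members and lower at 1 (14 and 1 adjusted over the list alone, camera adjusted p = 7.4e-09, adjusted p = 0.26 with an estimated correlation). Adgre1 (13733), the F4/80 antigen, was at 51.8 ± 10.9 against 4.34 ± 2.60 RPKM. It was at 91.2 ± 4.11 RPKM in cDC2, so its rise over cDC1 is shared with cDC2. Mertk (17289), a receptor kinase that binds dying cells, was at 13.6 ± 2.47 against 1.42 ± 0.405, and C1qc (12262), a chain of complement C1q, at 93.8 ± 55.9 against 12.0 ± 5.45, while Treml4 (224840) was lower, at 32.9 ± 11.6 against 102 ± 7.82. Fc and complement receptors were higher at 11 of 19 members (13 adjusted over the list alone, adjusted p = 7.1e-05, and 0.26 with an estimated correlation), among them C1qb (12260), C1qa (12259) and Fcer1g with log2 fold changes of 2.52 ± 0.33, 2.51 ± 0.27 and 2.22 ± 0.28. NK cell genes were higher at 7 of 15 members (9 adjusted over the list alone, adjusted p = 8.8e-05, and 0.44 with an estimated correlation). Ncr1 (17086), the NKp46 receptor, was at 25.3 ± 5.97 against 4.84 ± 0.774 RPKM. Xcl1 (16963), the ligand of Xcr1, was at 54.2 ± 38.1 against 9.58 ± 5.17 (adjusted p = 0.014, 0.052 without cDC1 replicate 2 and 0.00016 to 0.052 over all settings tried). Monocyte genes were higher at 8 and lower at 1 of 17 members (9 and 1 adjusted over the list alone, adjusted p = 0.0066, and 0.60 with an estimated correlation). Ace was at 6.97 ± 0.178 against 0.688 ± 0.308 RPKM and Csf1r (12978), the receptor for M-CSF, at 86.7 ± 15.5 against 22.2 ± 9.91. That call was lost without mcDC replicate 3 (0.099, and 0.00073 to 0.099 over all settings tried). The libraries scored 5.12 ± 0.32 in mcDC and 3.38 ± 0.26 in cDC1 as the mean log2(RPKM + 1) of the macrophage list, and 4.09 ± 0.54 and 2.94 ± 0.25 for the NK cell list (two-sided exact permutation p = 0.10 each, the smallest that 3 against 3 libraries allow).

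Interferon stimulated genes were higher in mcDC than in cDC1 at 13 and lower at 3 of 35 members (15 and 4 adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.44 with an estimated correlation). Oas2 was at 13.3 ± 3.56 against 0.424 ± 0.456 RPKM and Ddx58 at 12.8 ± 0.546 against 1.81 ± 0.164. Genes of cholesterol synthesis and efflux were higher at 10 and lower at 1 of 25 (15 and 2 adjusted over the list alone, adjusted p = 0.0021, and 0.39 with an estimated correlation). Pltp (18830), a phospholipid transfer protein, was at 14.5 ± 1.42 against 0.966 ± 0.559 RPKM. Nr1h3 (22259), the sterol-sensing receptor LXR alpha, was at 13.4 ± 5.29 against 1.30 ± 0.646. Genes of apoptotic cell uptake were higher at 11 and lower at 3 of 23 (14 and 3 adjusted over the list alone, adjusted p = 0.027, and 0.44 with an estimated correlation). Cd300lf was at 53.9 ± 12.8 against 5.90 ± 4.36 RPKM, and Axl (26362), a receptor kinase related to Mertk, at 23.2 ± 3.57 against 4.99 ± 1.68. That list lost its call without mcDC replicate 1 (0.054), 2 (0.057) or 3 (0.051), with 0.0057 to 0.064 over all settings tried. With the title run as a block camera called dissociation stress genes higher (1 of 22 higher without the block, 1 adjusted over the list alone, adjusted p from 0.38 to 0.026) and ribosomal protein genes lower in mcDC (0 of 75 called by limma, 0 adjusted over the list alone, 0.11 to 0.032). Both had adjusted p = 0.90 with an estimated correlation and no block.

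Against cDC2, mcDC had more NK cell, macrophage and cDC1 transcripts and fewer granulocyte and monocyte transcripts. The granulocyte difference lay with cDC2. The mean log2(RPKM + 1) of the neutrophil list was 1.22 ± 0.39 in mcDC, 1.10 ± 0.42 in cDC1 and 2.63, 4.62 and 5.05 in the cDC2 libraries. Whether other cells in the cDC2 sort carried these transcripts was not tested. Xcl1 was at 54.2 ± 38.1 RPKM in mcDC and 2.53 ± 1.19 in cDC2 (log2 fold change 3.80 ± 0.50, limma adjusted p = 0.0048). Mertk was at 13.6 ± 2.47 against 0.734 ± 0.110 (3.07 ± 0.20, 0.00018). Vcam1 (22329), an adhesion molecule of splenic macrophages, was at 61.3 ± 12.6 against 7.66 ± 2.18 (2.86 ± 0.22, 0.00042) and Klrc1 (16641), the NKG2A receptor, at 23.6 ± 13.8 against 2.18 ± 0.258 (2.78 ± 0.38, 0.0053). Jchain (16069), the joining chain of polymeric antibodies, was at 186 ± 94.7 against 18.8 ± 9.54 RPKM (3.18 ± 0.57, 0.016), and its adjusted p was 0.061, 0.086 and 0.063 without cDC2 replicate 1, cDC2 replicate 2 and mcDC replicate 2 (0.00043 to 0.086 over all settings tried). The 5 largest falls were S100a9 (20202), S100a8, Ngp (18054), Camp (12796) and Chil3 (12655), all granulocyte or monocyte products, with log2 fold changes of -5.49 ± 0.97, -4.92 ± 1.11, -4.85 ± 1.12, -4.80 ± 1.11 and -4.44 ± 0.67. S100a9 was at 5.03 ± 5.17 against 275 ± 219 RPKM (adjusted p = 0.014, 0.080 without cDC2 replicate 2, 0.066 without cDC2 replicate 3). Camp had no read in any mcDC library and was at 57.1 ± 52.9 RPKM in cDC2, at least 216-fold lower by a floor of 3 counts over the mcDC group, which covers counting error only. Leaving out cDC2 replicate 1 kept the calls of S100a8, Ngp and Camp, and leaving out mcDC replicate 3 those of S100a8 and Ngp, while leaving out any other library ended them (adjusted p up to 0.18, 0.20 and 0.20), and with voom the adjusted p of S100a9, S100a8, Ngp, Camp and Chil3 was 0.23, 0.23, 0.51, 0.57 and 0.40. Over all settings tried the lowest were 0.00070, 0.00011, 0.0041, 0.0010 and 0.00043.

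Between mcDC and cDC2, 438 of 11971 genes passed limma, 247 higher and 191 lower in mcDC (56.4% higher). The count was 243 with these groups fitted alone, 773 with the title run as a block, and 718 with mcDC replicate 3 left out as well. Of the 438, 189 higher and 130 lower genes differed by at least 2-fold, and the libraries did not overlap at 2588 genes (21.6%, chance gives 10%). Median-of-ratios scaling gave 201 higher and 254 lower (44.2% higher) and voom 197 and 236 (45.5%). The count was 279, 158 and 188 without cDC2 replicates 1, 2 and 3, and 896 without mcDC replicate 1. Irf8 was higher in mcDC, at 368 ± 147 against 76.3 ± 22.7 RPKM (adjusted p = 0.0072), as were Xcr1 at 15.7 ± 4.73 against 2.45 ± 0.442 (0.0018) and Clec9a at 60.9 ± 13.9 against 20.5 ± 3.67 (0.0038). Cd8a was at 5.81 ± 3.36 against 1.30 ± 0.101 RPKM (adjusted p = 0.018, 0.063, 0.086 and 0.069 without cDC2 replicates 1, 2 and 3, and 0.0017 to 0.098 over all settings tried). Itgam was lower in mcDC, at 13.8 ± 3.34 against 101 ± 18.4 RPKM (0.00042). Sirpa (170 ± 37.7 and 274 ± 6.33 RPKM, adjusted p = 0.42), Cd4 (59.6 ± 32.7 and 100 ± 20.6, 0.38), Irf4 (24.4 ± 13.3 and 27.1 ± 8.08, 0.85), Batf3 (184 ± 56.8 and 118 ± 5.73, 0.13), Itgae (2.53 ± 2.14 and 0.360 ± 0.0759, 0.25), Flt3 (174 ± 26.3 and 146 ± 14.9, 0.42) and Zbtb46 (34.9 ± 9.43 and 34.6 ± 4.72, 0.98) did not pass. Itgax (325 ± 81.7 and 462 ± 54.3 RPKM, adjusted p = 0.19) and Siglech (4.03 ± 1.02 and 0.684 ± 0.0839, 0.075) passed with the title run as a block (0.022 and 0.044).

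**Figure D2:**
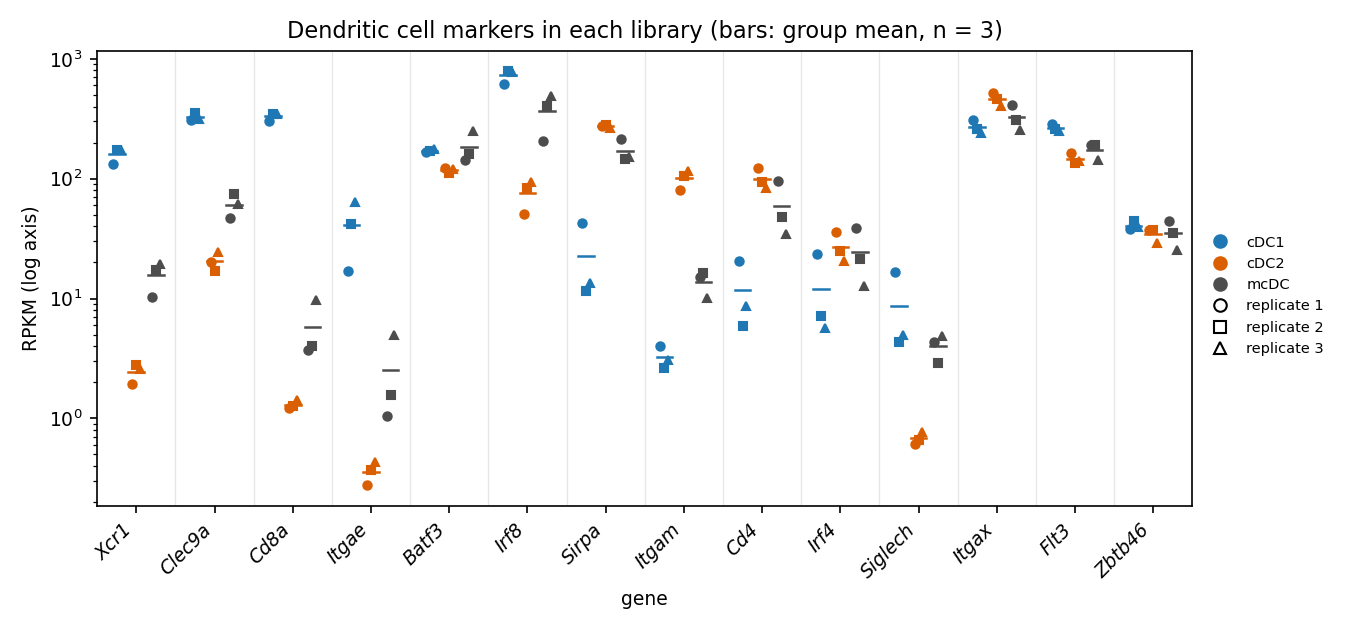
RPKM of 14 dendritic cell genes in each library on a log axis, with colour for the subset, symbol for the replicate and a bar at the mean of each group (n = 3). Xcr1, Clec9a and Cd8a are highest in cDC1 and above cDC2 in every mcDC library, while Itgam is at 101 RPKM in cDC2 and 13.8 in mcDC.

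Camera called 15 of 34 lists between mcDC and cDC2, 5 higher and 10 lower in mcDC, while with an estimated correlation it called 0 (8 at an unadjusted p under 0.05) and fry called 12. Of 22 cDC1 identity genes, 12 were higher in mcDC (16 adjusted over the list alone, camera adjusted p = 5.4e-13, adjusted p = 0.16 with an estimated correlation). Of 23 cDC2 identity genes, 6 were lower (9 lower and 1 higher adjusted over the list alone, adjusted p = 9e-07, and 0.22 with an estimated correlation). Clec10a (17312) and Mgl2 (216864), lectins for galactose-type sugars, were at 3.32 ± 2.31 against 44.5 ± 23.5 RPKM and at 0.223 ± 0.0943 against 7.67 ± 3.58, and Mgl2 lost its call with voom (0.055, and 0.0015 to 0.055 over all settings tried). Red pulp macrophage genes were higher at 11 and lower at 1 of 17 members (13 and 3 adjusted over the list alone, adjusted p = 4.4e-09, and 0.17 with an estimated correlation). Beside Mertk and Vcam1 they included Cd5l (11801), a macrophage survival factor, at 21 ± 13.2 against 1.98 ± 0.479 RPKM. Slc40a1 (53945), the iron exporter ferroportin, was at 51.8 ± 10.6 against 6.98 ± 1.30. NK cell genes were higher at 7 of 15 members (12 adjusted over the list alone, adjusted p = 1.2e-10, and 0.17 with an estimated correlation). Ncr1 was at 25.3 ± 5.97 against 3.57 ± 1.09 RPKM and Il2rb (16185), a chain of the IL-2 and IL-15 receptors, at 31.3 ± 5.97 against 5.13 ± 1.16. T cell genes were higher at 2 of 17 members (8 adjusted over the list alone, adjusted p = 0.00048, and 0.42 with an estimated correlation), namely Tcf7 and Lck. Tcf7 (21414), a transcription factor of T and innate lymphoid cells, was at 61.0 ± 12.1 against 17.3 ± 6.54 RPKM. The kinase Lck (16818) was at 13.3 ± 6.61 against 3.50 ± 0.659. Lck lost its call without cDC2 replicates 1, 2 or 3 (0.088, 0.13, 0.074) or mcDC replicate 2 (0.051), with 0.0032 to 0.13 over all settings tried. Mature and migratory genes were higher at 4 of 22 members (8 adjusted over the list alone, adjusted p = 0.015, and 0.56 with an estimated correlation). The inhibitory ligand Cd200 (17470) was at 11.5 ± 3.80 against 3.38 ± 0.703 RPKM, and the list lost its call without mcDC replicate 1 (0.27, and 9.9e-06 to 0.27 over all settings tried).

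Neutrophil genes were lower in mcDC than in cDC2 at 9 of 15 members (12 adjusted over the list alone, camera adjusted p = 1.2e-13, adjusted p = 0.16 with an estimated correlation), and their mean log2(RPKM + 1) was 1.22 ± 0.39 in mcDC against 2.63, 4.62 and 5.05 in the cDC2 libraries. Monocyte genes were lower at 8 of 17 members (9 lower and 1 higher adjusted over the list alone, adjusted p = 2.3e-09, and 0.19 with an estimated correlation). Ace was at 6.97 ± 0.178 against 94.0 ± 11.5 RPKM and Lyz2 at 211 ± 9.63 against 1110 ± 386. Interferon stimulated genes were lower at 5 of 35 members (15 adjusted over the list alone, adjusted p = 1.4e-09, and 0.16 with an estimated correlation). Oas3 (246727) was at 3.41 ± 0.767 against 11.8 ± 2.66 RPKM and Oasl2 at 8.60 ± 1.69 against 24.2 ± 4.87. Toll-like and nucleic acid sensors were lower at 3 and higher at 2 of 29 members (5 and 2 adjusted over the list alone, adjusted p = 0.00014, and 0.11 with an estimated correlation). Tlr8 (170744), a receptor for RNA fragments, was at 2.15 ± 0.243 against 6.23 ± 1.26 RPKM (adjusted p = 0.014, 0.087 without cDC2 replicate 2, 0.087 without cDC2 replicate 3, and 0.0077 to 0.11 over all settings tried). Cytokines were lower at 1 of 16 members (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0039, and 0.19 with an estimated correlation), namely Il1rn (16181), the antagonist of the IL-1 receptor, at 1.03 ± 0.163 against 8.83 ± 1.57 RPKM, and the list lost its call without mcDC replicate 2 (0.054, and 0.00054 to 0.054 over all settings tried). C-type lectins were lower at 10 and higher at 2 of 30 (11 and 6 adjusted over the list alone, adjusted p = 0.0039, and 0.39 with an estimated correlation), with 0.096 without cDC2 replicate 3 and 2e-04 to 0.096 over all settings tried.

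Fc and complement receptors were lower in mcDC than in cDC2 at 4 and higher at 3 of 19 members (8 and 3 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.31 with an estimated correlation), with complement C3 (12266) at 2.10 ± 0.147 against 12.3 ± 3.59 RPKM. That list lost its call without cDC2 replicate 3 (0.092), mcDC replicate 1 (0.091) or mcDC replicate 2 (0.054) and with quantile normalization (0.076) or median-of-ratios scaling (0.051), and its adjusted p was 0.0011 to 0.092 over all settings tried. Genes of the phagosomal NADPH oxidase and proton pump were lower at 1 of 21 members (2 adjusted over the list alone, adjusted p = 0.00025, and 0.16 with an estimated correlation), and those of MHC class II presentation at 1 of 19 (1 adjusted over the list alone, adjusted p = 0.00081, and 0.16 with an estimated correlation). The class II member was the protease Ctss (13040), at 555 ± 30.2 against 884 ± 88.4 RPKM (adjusted p = 0.030). Among the libraries left out, Ctss kept its call only without cDC1 replicate 1, mcDC replicate 1 or mcDC replicate 3, with adjusted p from 0.011 to 0.14 over all settings tried. The invariant chain Cd74 (16149) did not pass, at 9790 ± 1260 and 12000 ± 728 RPKM (adjusted p = 0.64). With the title run as a block camera called 4 further lists, which had adjusted p = 0.81, 0.48, 0.48 and 0.88 with an estimated correlation and no block. The erythroid and platelet list (0 of 12 called by limma without the block, 0 adjusted over the list alone, adjusted p from 0.088 to 0.0019) and the plasmacytoid list (2 higher of 19, 5 higher and 1 lower adjusted over the list alone, 0.051 to 0.048) were called higher in mcDC, and apoptotic cell uptake (3 lower and 4 higher of 23, 7 and 5 adjusted over the list alone, 0.050 to 0.039) lower. Oxidative phosphorylation (0 of 38 called by limma, 0 adjusted over the list alone, 0.24 to 0.048) was called higher with the block and in the opposite direction without mcDC replicate 3 (0.039), so no direction is drawn for it.

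Genes that set mcDC apart from both conventional subsets were mostly higher. Intersecting the limma comparisons, 108 genes were higher in mcDC than in both and 11 were lower, with each pair of groups fitted alone 59 and 7, with the title run as a block 179 and 27, and with mcDC replicate 3 left out as well 180 and 26. The count of lower genes was 23 with quantile normalization and 24 with median-of-ratios scaling. Independent calls would share 23.5 higher and 11.2 lower genes without such rescaling, but calls against the same mcDC libraries are not independent. Simulated groups without any effect that shared the mcDC libraries gave a mean of 0 higher and 0.02 lower genes over 50 simulations. Without an effect hardly any gene is called in either comparison. The simulation therefore cannot tell how far the shared mcDC libraries raise the overlap among genes that are called. The 10 leading genes were C1qc, Mertk, Cd5l, Slc40a1 and Itgad (381924), an integrin chain of red pulp macrophages, Xcl1, Klrc1 and Ncr1 of NK cells, Ccr3 (12771), the eotaxin receptor, and Prss2 (22072), a trypsinogen. Ccr3 was at 12.5 ± 5.27 RPKM in mcDC, 1.86 ± 0.389 in cDC1 and 1.11 ± 0.75 in cDC2. Itgad was at 15.1 ± 2.19, 2.92 ± 1.16 and 2.45 ± 0.313. Prss2, at 6.47 ± 4.18, 0.110 ± 0.190 and 0.0973 ± 0.169, lost its call against cDC2 (adjusted p = 0.012) without cDC2 replicate 2 (0.068) or mcDC replicate 2 (0.051), with 0.00084 to 0.077 over all settings tried. Among the lower genes Pid1 (98496), which dampens insulin signalling, was at 30.3 ± 0.760 RPKM against 57.1 ± 2.76 in cDC1 and 51.9 ± 3.22 in cDC2. Ptafr (19204), the receptor for platelet-activating factor, was at 12.9 ± 1.91 against 22.1 ± 2.75 and 27.0 ± 0.998. The higher count was 66, 64, 47, 57 and 237 without cDC1 replicate 2, cDC2 replicates 1, 2 and 3 and mcDC replicate 1. The lower count was 5 and 6 without cDC1 replicates 2 and 3, 5, 6 and 4 without cDC2 replicates 1, 2 and 3, and 45 without mcDC replicate 1.

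**Figure D3:**
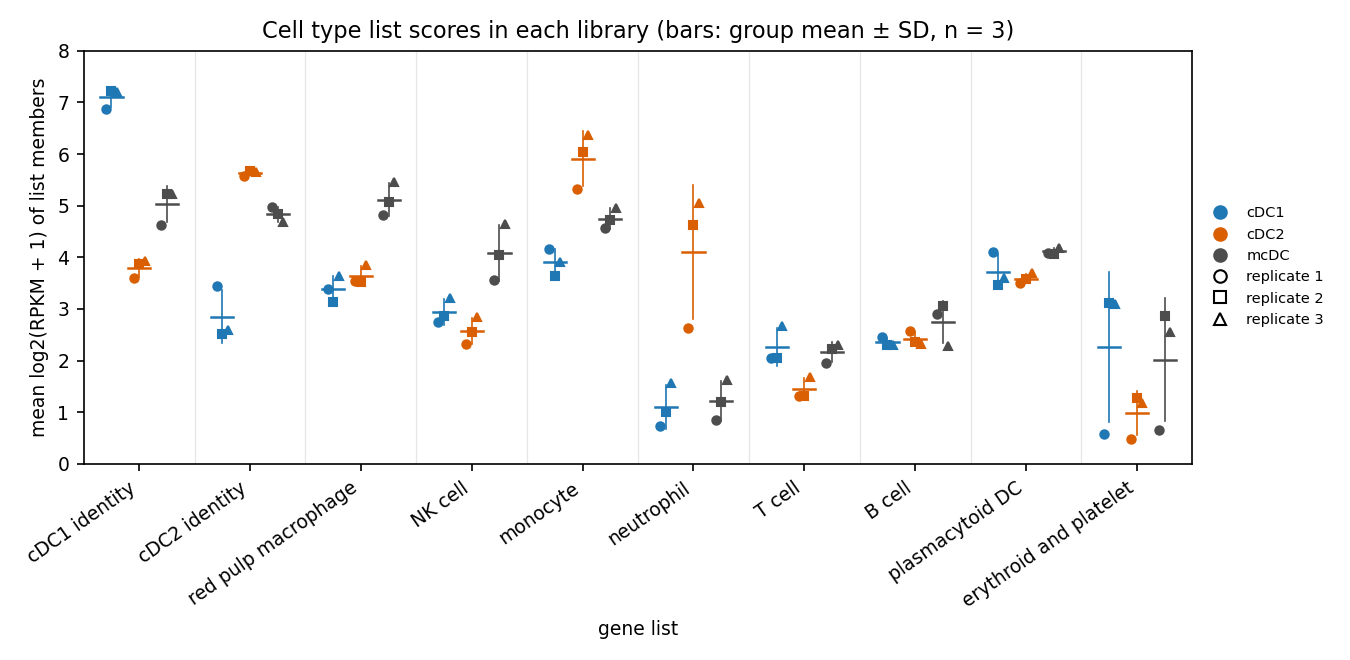
Mean log2(RPKM + 1) of the tested members of 10 cell type lists in each library, with colour for the subset, symbol for the replicate and bars for the group mean ± SD (n = 3). The red pulp macrophage list is at 5.12 ± 0.32 in mcDC, 3.38 ± 0.26 in cDC1 and 3.65 ± 0.19 in cDC2, and the neutrophil list ranges from 2.63 to 5.05 within cDC2.

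mcDC lay nearer cDC2 than cDC1 at most of the genes that part the conventional subsets. In a fit without the mcDC libraries, 3724 genes differed between cDC1 and cDC2, 1754 higher in cDC1 and 1970 higher in cDC2. At 30.5% of them the mcDC mean lay nearer cDC1 and at 69.5% nearer cDC2, with 25.7%, 32.2% and 43.8% nearer cDC1 in mcDC replicates 1, 2 and 3 (33.9 ± 9.2%, mean ± SD). On a scale from 0 at the cDC1 mean to 1 at the cDC2 mean the median position was 0.69, and at 988 genes (26.5%) mcDC lay outside the range of the cDC means. Among cDC2 genes, Itgam and Clec10a stayed far below cDC2 in mcDC, at 13.8 ± 3.34 and 3.32 ± 2.31 RPKM, while Dtx1, at 87.6 ± 19.1 RPKM, stood far above cDC1. Genes are not independent replicates, so these shares describe the libraries and carry no test.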

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

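No gene or list called in the comparisons turned direction in any setting that still called it. Of the lists called, 13 of 15 between cDC1 and cDC2, 9 of 11 between mcDC and cDC1 and 11 of 15 between mcDC and cDC2 kept the call whichever library was left out, as did 100 of 120, 87 of 120 and 33 of 75 named genes, so mcDC against cDC2 depends most on single libraries. Leaving out 1 library gave 951 to 2601 genes for mcDC against cDC1, 158 to 896 for mcDC against cDC2, 1547 to 3467 for cDC1 against cDC2, 47 to 237 genes higher in mcDC than in both others and 4 to 45 lower. Each pair of groups fitted alone gave 1097, 243 and 3724 genes, 59 higher and 7 lower. The main fit shares its estimate of spread between groups, while Pearson's r between replicates was 0.898 to 0.961 in mcDC, 0.969 to 0.986 in cDC1 and 0.978 to 0.990 in cDC2. Its p-values may therefore be too small for mcDC and too large for cDC1 against cDC2. With the title run as a replicate block the counts were 2474, 773 and 2942 for mcDC against cDC1, mcDC against cDC2 and cDC1 against cDC2, of which 1824, 431 and 2324 were called without it, with 179 higher and 27 lower than both. Among the 34 lists it changed no other call than those printed above. With mcDC replicate 3 left out as well, the counts were 3003, 718 and 4274, with 180 higher and 26 lower. The count of genes lower than both was 23 with quantile normalization and 24 with median-of-ratios scaling. The list calls rest on the preset correlation, since with an estimated correlation camera called 0, 0 and 0 lists for mcDC against cDC1, mcDC against cDC2 and cDC1 against cDC2, while fry called 18 for mcDC against cDC1. Lists that were not called could be called in opposite directions as libraries were left out. The oxidative phosphorylation list had adjusted p from 0.0068 to 0.96 for mcDC against cDC1, with the direction turned without mcDC replicate 3 (0.031), and from 1.8e-05 to 0.99 for mcDC against cDC2, turned without mcDC replicate 3 (0.039). The ribosomal protein list had 6.2e-10 to 0.84 for mcDC against cDC2, turned without mcDC replicate 1 (0.017). The share of genes at which mcDC lay nearer cDC1 was 26.6% to 38% over the settings tried.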

Other observations

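Gata3, Il7r and Il18r1, which innate lymphoid cells express, were among the genes higher in mcDC than in both conventional subsets, although no list of these cells was tested. At the preset correlation camera also called the NK cell list higher against both subsets and the T cell list higher against cDC2. The mean log2(RPKM + 1) of the T cell list was 2.16 ± 0.19 in mcDC, 2.26 ± 0.36 in cDC1 and 1.44 ± 0.21 in cDC2. For that list as a whole the difference from cDC2 is therefore shared with cDC1. Which cells the transcripts come from was not tested. The genes of this and the next paragraph lie outside the naming rule and were chosen after their values were seen, with RPKM and limma results for n = 3 libraries per group. Gata3 (14462), a transcription factor of type 2 innate lymphoid cells, was at 2.45 ± 1.25 RPKM in mcDC against 0.470 ± 0.0868 in cDC1 and 0.178 ± 0.0339 in cDC2 (adjusted p = 0.024 and 0.024), Il7r (16197), the IL-7 receptor, at 12.8 ± 1.53 against 8.17 ± 1.56 and 4.54 ± 0.0508 (0.039 and 0.0046), and Il18r1 (16182), an IL-18 receptor chain, at 5.93 ± 1.57 against 1.73 ± 0.364 and 0.954 ± 0.211 (0.0030 and 0.0037).

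Mrc2, Maf and Igf1, which tissue macrophages express, were also among these genes, and no further macrophage list was tested. Mrc2 (17534), a collagen uptake receptor, was at 6.96 ± 1.80 RPKM against 0.342 ± 0.132 in cDC1 and 1.79 ± 0.518 in cDC2 (limma adjusted p = 0.00012 and 0.0074), Maf (17132), a macrophage transcription factor, at 6.47 ± 1.72 against 1.72 ± 0.0498 and 1.78 ± 0.446 (0.0023 and 0.0085), and Igf1 (16000), a growth factor, at 2.25 ± 0.679 against 0.360 ± 0.181 and 0.269 ± 0.0717 (0.0046 and 0.011).

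All tests of this pattern were chosen after the result was seen. Macrophage and NK cell transcripts in mcDC could be the subset's own or come from other cells in the sort, whose gate was not given in the sources used here. Of the red pulp macrophage list 10 of 17 members (58.8%) were higher in mcDC than in both others, and of the NK cell list 6 of 15 (40%). These counts restate the pattern and decide neither case, and 16 of the 17 and 12 of the 15 members were above 1 RPKM in both conventional subsets and 7 and 2 stand in another list. With all libraries thinned to one depth the log2 fold changes kept a median of 99.1% of their size for the macrophage and 99.4% for the NK cell members (73% to 109.4%). Thinning leaves the expected RPKM of a gene as it was, so sizes near these were given in advance and do not test lower depth of mcDC as a cause. At one depth 10 of 10 macrophage members kept their calls, but just 4 of 6 NK cell members. Reads were thinned in a single random draw, so which calls are lost may change with the draw. Of the members lost, chosen after their values were seen, Klre1 (243655) went from a log2 fold change of 1.18 ± 0.28 to 0.86 ± 0.28 against cDC1 (SE, limma adjusted p = 0.019 to 0.074) and from 1.86 to 1.81 against cDC2, and Klrb1c (17059) from 1.89 to 1.86 and from 1.88 ± 0.40 to 1.75 ± 0.40 (0.036 to 0.052), a change smaller than its SE in a call near the threshold.

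All tests of this pattern were chosen after the result was seen. mcDC values between those of cDC1 and cDC2 could come from a mix of only these cells, in which genes far higher in cDC2 would give a single share of cDC2 RNA. Of 114 called genes at least 8-fold higher in cDC2 and with at least 10 RPKM there, 15 in the neutrophil or monocyte list were left out. Of the remaining 99, 14 gave under 25% in all 3 mcDC libraries, such as Itgam, and 19 gave over 50%. The neutrophil list had a mean log2(RPKM + 1) of 2.63 to 5.05 over the cDC2 libraries. Granulocyte or monocyte RNA there could lower the share of genes outside these lists too, so the spread of shares alone does not exclude a mix. The median shares of cDC1 and cDC2 RNA added up to 49.8%, 47% and 49.1% in mcDC replicates 1, 2 and 3, 49.8% at most. This argues against libraries of cDC1 and cDC2 RNA alone, although the cDC2 shares carry the same limit. A mix of only these cells cannot exceed both subsets, yet limma called 108 genes higher in mcDC than in both. With 1 library left out the count was 47 to 237. These genes also argue against a mix of only these cells. A share of such cells, a subset of cDC2 or further cell types remain possible.

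Tests of this pattern were set before their results were seen. Libraries of a title run deviated together, with a mean correlation of 0.39. With each library's trend over gene length taken out it was 0.31, so this trend may not be the whole cause. With all libraries at one depth it was 0.36. Thinning leaves the expected RPKM of a gene as it was, so a value near 0.39 was given in advance and does not test depth. A shared day or shared animals could not be tested.

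The splits below were set before their results were seen, except those into 3 groups that part the title runs. With 10 splits of 6 libraries, too few for a share under 0.05, the real split alone (1 of 10) reached its gene count in each comparison, 1845, 438 and 2344 for mcDC against cDC1, mcDC against cDC2 and cDC1 against cDC2, with 0 as the highest other, although up to 1866, 1938 and 281 genes had an unadjusted p under 0.05 in another split. In every other split libraries of different subsets share a group, so differences between subsets widen its spread. Its gene count can be 0 for that reason alone, and the contrast does not measure chance. List counts stood out less, as 2, 1 and 5 of 10 splits had at least the 11, 15 and 15 lists called. The highest other list counts were 13, 13 and 18, so the real split alone reached its count just for mcDC against cDC2. Among splits that part all title runs, as the real one does, the highest other were 13, 13 and 17. Of 100 splits into 3 groups, 2 had at least 108 genes higher and 2 at least 11 lower in 1 group than in both others, the real one and the one with cDC1 in the place of mcDC (598 and 764), but just 10 of these splits part every title run as the real one does. Of 100 splits drawn among those that do, 6 had at least 108 genes higher and 6 at least 11 lower, a share that does not exclude chance. All of the 6 have a whole subset as the group set apart, so they carry differences between subsets and their share does not measure chance alone. Where that group mixed subsets the counts were 0. The wider spread within mixed groups can give this by itself, and it may lower the counts of the first 100 splits too.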
